A study of Drosophila melanogaster with 2 samples.

How the data were processed

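Chromatin from whole embryos of a transgenic line expressing GFP-tagged CG6683 was sonicated, and fragments of 200 to 800 bp were the stated size range, per the labels. Both samples are labelled as biological replicates of 1 group, numbered 2 and 3, and each peak list was made against a control alignment. The age label of the samples was not interpretable, so the age range of 6 to 24 hours was taken from the source name. The aligner, the peak caller and the reproducibility threshold are not given in the sources used here.

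The deposited files are peak lists on the builds dm6 and dm3. For each build there was 1 optimal list after IDR thresholding and 1 list of pooled candidates, both for the whole series, and 1 candidate list per replicate. Each candidate list held 30000 peaks. The signal value per peak is as deposited by the authors, with no normalization stated, and was used to rank and describe peaks within a list. The deposited lists also hold a −log10 q value per peak. Every peak of the optimal dm6 list had the same one, 3.03, which is the highest value in the pooled list, so it could not rank peaks and was not used further. The position of the summit within each peak was taken from the deposited lists too. On each build the optimal list was identical to the upper part of the pooled candidates by signal (2980 of 2980 peaks on dm6 and 3965 of 3965 on dm3), so the pooled candidates below it are peaks of lower signal from the same libraries, not an independent control. Read counts are in none of the files analysed here, so depth per sample is unknown, and intervals describe variation across peaks and genes only.

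Positions were annotated with Ensembl release 115 (BDGP6.54) and sequences were taken from the Release 6 genome, both in dm6 coordinates. All dm6 peaks lay within the chromosome lengths of that genome. The dm3 lists were compared without converting coordinates. Peaks on the arms 2L, 2R, 3L, 3R, 4 and X were analysed, and coordinates are 1-based. A summit was called promoter when it lay within 500 bp of the start of any transcript of a protein-coding gene. Other summits were assigned to 5' UTR, 3' UTR, coding exon, intron, non-coding gene or intergenic sequence, in that order. The comparison set was the pooled candidates that overlapped no optimal peak. Shares were compared with two-sided Fisher's exact tests, and promoter shares and replicate overlap also with 1000 circular shifts of the summits along each arm. Chromosome shares were tested with exact binomial tests against each arm's share of pooled candidates. Correlations and differences of medians were tested with 100000 permutations. The intervals of the median offset used 10000 bootstrap resamples and that of rho 1000. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Neighbouring peaks and genes that share a promoter are not independent, and p-values measure the contrast between sets of peaks, not the spread between embryos.

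Replicates were compared through the 2964 candidates of highest signal in each list, as many as there are optimal peaks on the main arms. For the gene lists, the background was the 7038 protein-coding genes with a pooled candidate summit within 500 bp of a start. For motifs and 6-mers, the sequence within 100 bp of each summit was compared with windows of the same size centred 500 bp to either side, a word counting once per window on either strand. The rule for named genes took the nearest protein-coding start of the 25 optimal peaks of highest signal, up to 4 members of each list past the adjusted threshold, up to 2 of each other list, and CG6683. The 10 leading 6-mers were those with the lowest p among those higher at summits and present in at least 5% of them. The gene lists, motifs, naming rule, alternatives and the tests of the report were fixed before the data were examined, and the closing section says which of its own tests were chosen later.

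The alternatives were promoter windows of 200 and 1000 bp, the upper 50% of optimal peaks by signal, either replicate's own list in place of the optimal list, other rules for shared peaks, the dm3 lists, GC-matched candidates (in bins of 2%) as sequence background, peaks outside promoters, a window of 50 bp, and other backgrounds. The calculations were tested on simulated data. A planted promoter share of 60.0% in 3000 summits was recovered as 60.0%, a planted offset of -100.0 bp in 1800 summits as -100.0 bp, and 1 planted motif among 30 and 1 planted list among 26 were called with 0 false calls. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Mitochondrial peaks were left out of the comparisons because they cannot be placed on the arms, and their values are given in the closing section.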

Results

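The data describe where a GFP-tagged form of the fly protein CG6683 was found on chromatin in whole Drosophila melanogaster embryos aged 6 to 24 hours. The line carried CG6683 with GFP at its C-terminus, and chromatin was immunoprecipitated with an antibody against GFP and sequenced (ChIP-seq). There was 1 group with 2 biological replicates, labelled 2 and 3. Read depth is unknown, because the peak lists give no read counts, so the intervals below cover variation across peaks and genes only. Unless a build is named, positions are on dm6. The optimal list, the authors' list after IDR (irreproducible discovery rate) thresholding, held 2980 peaks, which were the 2980 of highest signal in the pooled candidate list. Of these, 2964 lay on the main chromosome arms and 16 on the mitochondrial genome, and the comparisons below used the 2964, of which 2791 had a candidate in both replicate lists. The peaks had a median width of 305 bp (range 111 to 1796 bp) over the whole list. The signal value is the authors' own score per peak. It ranged from 170.6 to 3257 on the main arms. The pooled candidate list held 29984 peaks on the main arms, and 26028 of these overlapped no optimal peak and served as the comparison set.

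The strongest CG6683-GFP peaks lay in introns and at promoters. The highest signal, 3257, was at 2L 6612366 to 6612979 in an intron of CG11050 (FBgn0031836). The summit was 1026 bp inside the gene from the nearest annotated transcription start site (TSS). The next was at 2L 480540 to 481377 (signal 3020) in an intron of ush, and the nearest start belonged to cbt (FBgn0043364), which encodes a zinc-finger transcription factor, at an offset of -1373 bp, where a negative offset is upstream. A peak at X 2703668 to 2704101 (signal 2763) covered the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter, with its summit at -25 bp. A peak at 3L 14759210 to 14759883 (signal 2071) lay in an intron of Trl (FBgn0013263), which encodes GAGA factor, 1524 bp from its nearest start. Of the 25 highest peaks, 14 had a summit within 500 bp of a protein-coding start, 9 lay in introns and 2 in non-coding genes. The 2 in non-coding genes were inside lncRNA:Vinr, with CG4004 as the nearest protein-coding gene at 4999 bp, and inside lncRNA:CR31840, with hll nearest at -2926 bp.

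Other promoters among these 25 were those of CG14100 (offset -94 bp), px (-199 bp), the glycolytic gene Gapdh2 (-150 bp), Tina-1 (-173 bp), Fkbp14 (-143 bp), mRpL41 (-139 bp), CG11309 (83 bp) and the Polycomb group gene ph-p (-448 bp). CG18549 (-112 bp), CG13390 (-83 bp), CG31145 (-169 bp), amon (-234 bp), which encodes a prohormone convertase, and PNPase (69 bp) completed the promoter group. The remaining intronic peaks had Lk6 (-993 bp), CG32772 (1269 bp), sbb (20092 bp), HmgZ (-571 bp), CG9663 (939 bp) and Tlk (2311 bp) as the gene of the nearest start. Lk6 and Tlk encode protein kinases and HmgZ a high-mobility-group protein. The lowest of the 25 signals was 1398. Every one of these 25 peaks had a candidate peak in both replicate lists. At Gapdh2, for example, the pooled signal of 1796 stood beside 789 in the list labelled replicate 2 and 1005 in the list labelled replicate 3.

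The next question was how far the replicates shared these sites. Of the 2964 strongest peaks labelled replicate 2, 65.6% had a summit within 200 bp of one of the 2964 strongest labelled replicate 3. Circularly shifted summits gave 0.853% on average and at most 1.52% in 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Among the optimal peaks, 77.0% were found in the upper 2964 of the list labelled replicate 2, 85.8% in that of replicate 3, and 65.3% in both. The optimal peaks were those of highest signal in the list pooled from these same replicates, so such shares are raised by that choice. Signal values at the 2791 optimal peaks with a candidate in both lists had a Spearman rho of 0.623 (95% bootstrap interval 0.594 to 0.650, two-sided permutation p = 1e-05, the smallest possible) and a Pearson r of log2 signal of 0.702 (two-sided permutation p = 1e-05). This correlation is across peaks, which are not independent replicates, and the peaks had been selected for high pooled signal. The replicate numbers name the lists on dm6. On dm3 the same intervals carry the other number, a discrepancy taken up in the closing section.

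**Figure D1:**
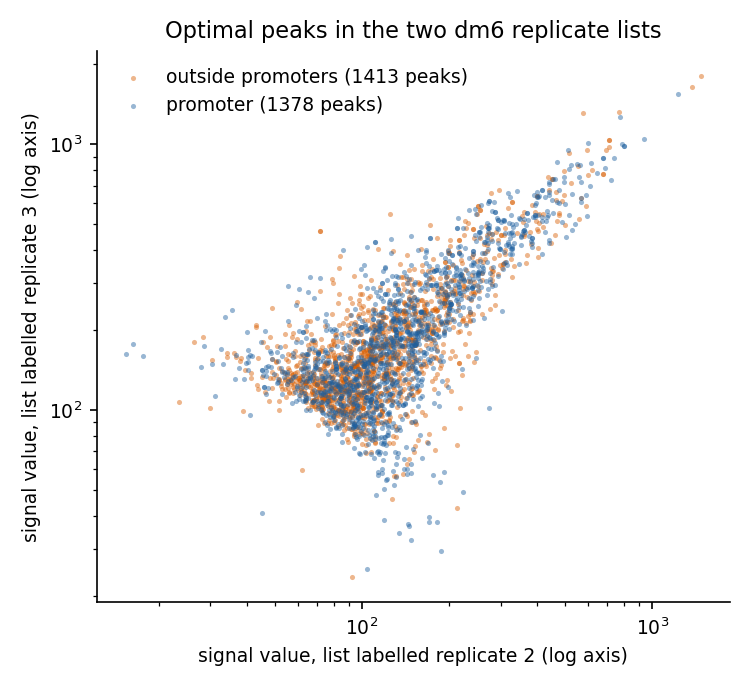
Signal values of the 2791 optimal peaks with a candidate in both dm6 replicate lists, replicate 2 on the x axis and replicate 3 on the y axis, both without units on log axes. Each point is 1 peak, coloured by whether its summit lies within 500 bp of a protein-coding start, and the points rise together with a Spearman rho of 0.623.

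CG6683-GFP peaks were concentrated at promoters. A total of 1468 of the 2964 summits (49.5%, exact 95% interval 47.7% to 51.3%) lay within 500 bp of a protein-coding start, against 29.9% of the other candidates (odds ratio 2.30, 95% interval 2.13 to 2.48, two-sided Fisher's exact p = 1.67e-98). Circularly shifted summits gave 11.5% on average and at most 18.4% (one-sided permutation p = 0.001, the smallest these shifts can give). The other candidates were themselves above random positions, of which 11.8% lay at promoters. With 1 group, promoter signal particular to CG6683 cannot be told apart from promoter signal that is not. Introns held 35.9% of the summits against 43.1% of the other candidates (Fisher's exact adjusted p = 8.02e-14). Exonic sequence away from promoters was nearly empty of optimal summits. Coding exons held 5 summits (0.169%) against 5.69% of the other candidates (odds ratio 0.0280, Fisher's exact adjusted p = 2.33e-62). Their share was 0.337% in the list labelled replicate 2 alone. The 3' UTRs held 27 summits (0.911%) against 5.90% (odds ratio 0.147, Fisher's exact adjusted p = 5.33e-42), and the 5' UTRs 20 (0.675%) against 313 of the other candidates (odds ratio 0.558, Fisher's exact adjusted p = 0.0115). Intergenic sequence held 10.8% against 12.5% (Fisher's exact adjusted p = 0.0119), a difference that turned to the opposite direction with a 200 bp promoter window (16.9% of optimal summits intergenic, Fisher's exact adjusted p = 0.00525). In the list labelled replicate 2 alone, the 5' UTR and intergenic differences did not pass (Fisher's exact adjusted p = 0.0521 and 0.192). Non-coding genes held 2.02% against 1.80%, which did not pass the test (Fisher's exact adjusted p = 0.384). The classes were not compared at matched GC content, which was lower at optimal summits (35.5%) than at the other candidates (40.5%).

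**Figure D2:**
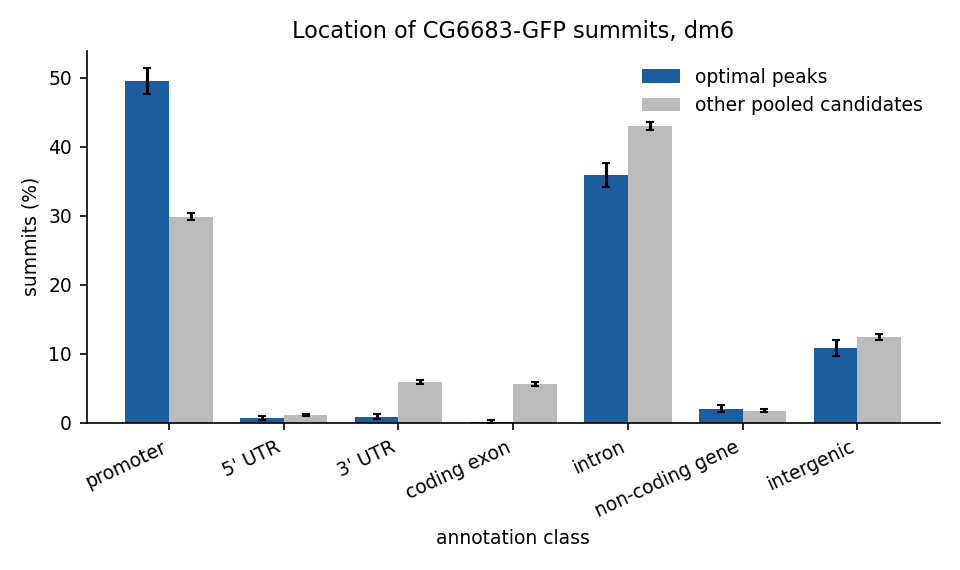
Percentage of summits in each annotation class for the 2964 optimal peaks (blue) and the 26028 other pooled candidates (grey), with exact 95% binomial intervals as error bars. Promoters hold 49.5% of the optimal summits against 29.9% of the other candidates, and coding exons 0.169% against 5.69%.

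Promoter summits sat mostly just upstream of the start. Their median offset was -121 bp (95% bootstrap interval -129 to -113 bp), with quartiles of -214 and -33.0 bp. Of those not exactly at a start, 1188 (81.1%, exact 95% interval 79.0% to 83.1%) were upstream (two-sided exact binomial p = 8.18e-135 against equal shares). The other candidates at promoters had a median offset of -21.0 bp, and 54.1% were upstream. Promoter peaks had a median signal of 277 (quartiles 207 and 414) against 252 (202 and 353) for the other optimal peaks, a difference of 24.4 (two-sided permutation p = 3e-05). The difference in signal was lost with a 200 bp window (7.84, permutation p = 0.167) and in the 2964 strongest peaks labelled replicate 2 alone (1.25, permutation p = 0.45).

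Chromosome 4, the small and largely heterochromatic chromosome of the fly, held few of the peaks. It carried 9 optimal peaks (0.304%) against a 1.22% share of the candidates, a ratio of 0.248 (two-sided exact binomial adjusted p = 9.01e-07). Against arm length the ratio was 0.302 (binomial adjusted p = 7.8e-05). In the list labelled replicate 2 alone, against that list's own candidates, it was 0.919 (binomial adjusted p = 0.926). In that labelled replicate 3 it was 0.201 (binomial adjusted p = 5.79e-12). The numbers of strong peaks on chromosome 4 were close, at 14 and 11 of the 2964 strongest. The ratios parted mainly because the lists held 154 and 554 candidates there. The X chromosome held 534 peaks, 18.0% against a candidate share of 19.9% (ratio 0.904, binomial adjusted p = 0.0281). Set against arm length instead, the X ratio was 1.02, and in the list labelled replicate 3 alone it was 0.976 (binomial adjusted p = 0.849). Among the upper 50% of peaks by signal the X ratio was 0.914 and did not pass (binomial adjusted p = 0.208). The arms 2L (555 peaks), 2R (559), 3L (626) and 3R (681) did not pass the test, with ratios between 1.01 and 1.07.

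Among 26 gene lists, the genes of cytosolic ribosomal proteins carried promoter peaks far more often than other genes. A promoter peak was present at 1855 of the 7038 genes with any pooled candidate summit within 500 bp of a start (26.4%). For the ribosomal protein genes it was 53 of 80 (66.3%, exact 95% interval 54.8% to 76.4%) against 25.9% of the other genes (odds ratio 5.62, 95% interval 3.50 to 8.84, two-sided Fisher's exact p = 6.76e-14, adjusted p = 1.76e-12 over the 26 lists). The members with the highest signal were RpL7 (FBgn0005593, 2L 10201004 to 10202321, signal 1165, summit at 32 bp), RpL41 (FBgn0066084, signal 874, -84 bp), RpL14 (FBgn0017579, signal 872, -48 bp) and RpL23A (FBgn0026372, signal 834, -103 bp).

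No other list passed the adjusted threshold, although single members of many had strong peaks. Mitochondrial ribosomal protein genes had a peak in 14 of 60 cases, among them mRpL41 (signal 1612) and mRpS10 (1381). Oxidative phosphorylation genes had 12 of 57, with ND-ASHI (569) and ND-MWFE (332) highest. Proteasome subunits had 5 of 29 (Rpn6, 230.0, and Rpn2, 226), aminoacyl-tRNA synthetases 8 of 21 (SerRS, 416, and IleRS, 377), translation factors 13 of 38 (eIF4EHP, 953, and eIF6, 901) and core splicing factors 7 of 27 (U2af50, 381, and SC35, 319). Genes of insulator and architectural proteins had a peak in 7 of 18 cases, with Chro (1393) and Cp190 (728) highest. Polycomb and Trithorax group genes had 8 of 29, with ph-p (1519) and brm (828) highest. Heat shock and chaperone genes had 5 of 14 (Hsp83, 1059, and Hsp27, 837), and cell cycle genes 6 of 30 (Dp, 589, and dup, 342). Genes of the Notch, Wnt, TGF-beta, Hedgehog, EGFR and FGF pathways had 9 of 39, with shn (893) and sgg (763) highest, and 18 of 44 in the list labelled replicate 2 alone (Fisher's exact adjusted p = 0.19).

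None of the lists of tissue genes passed the test, and the shares of some lay on opposite sides of that of other genes in the 2 replicate lists. Differentiated neuron genes had a peak in 2 of 24 cases (8.33%, Fisher's exact p = 0.0598, adjusted p = 0.626), and these were the neuronal RNA-binding protein gene elav (signal 1177) and comt (188). They had 3 of 20 in the list labelled replicate 3 alone, and 0 of 22 with a 200 bp window (Fisher's exact adjusted p = 0.0574). Muscle and mesoderm genes had 4 of 28 (Msp300, 413, and tin, 347, highest) and 7 of 25 in the list labelled replicate 3 alone, trachea and epidermis genes 2 of 19 (trh, 722, and par-6, 219) and cuticle protein genes 0 of 10 (Fisher's exact p = 0.0723, adjusted p = 0.626). Chemosensory receptor genes had 0 of 9. Trachea and epidermis genes had 8 of 22 in the list labelled replicate 2 alone and 3 of 21 in that labelled replicate 3, and glial genes 4 of 10 and 2 of 11. The excesses in the list labelled replicate 2 did not pass either (Fisher's exact adjusted p = 0.67 and 0.763). Glial genes in the optimal list had 2 of 10 (moody, 793, and Gli, 240), and the gut, fat body and hemocyte list 2 of 10 (fkh, 1166, and bowl, 432), with 4 of 11 in the list labelled replicate 2 alone. Neuroblast and proneural genes had 4 of 13 (numb, 580, and E(spl)m3-HLH, 442, highest), ecdysone response genes 4 of 16 (Eip75B, 570, and Eip63F-1, 405) and germ line and piRNA genes 3 of 14 (orb, 499.8, and bgcn, 496). Segmentation transcription factors had 1 of 3, which was bowl. The eggshell list, taken by symbol pattern, had 1 of 2, and this member was Cp190, which is not an eggshell gene. None of the 12 Hox genes or the 111 histone genes of the replicative cluster had a candidate summit at a start, so neither list was testable. With all 13968 protein-coding genes as background, 4 lists passed instead of 1: the ribosomal protein list was higher, and the histone, cuticle protein and chemosensory receptor lists were lower, with 0 genes with a peak in each.

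**Figure D3:**
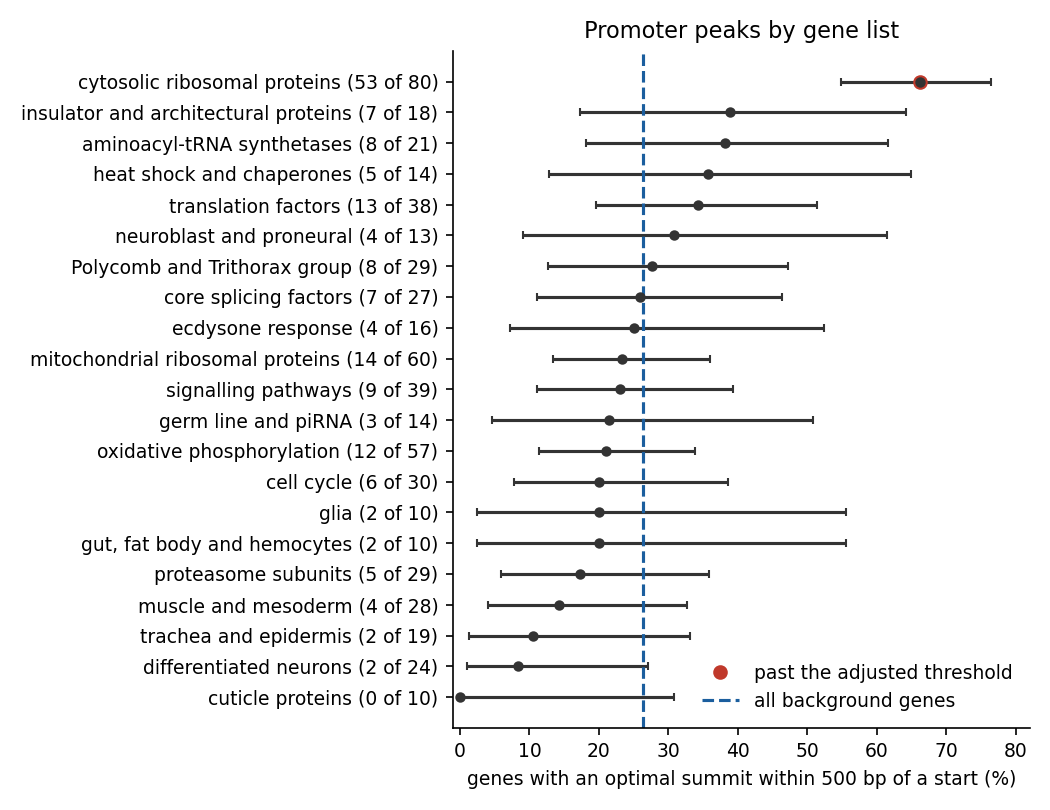
Percentage of each list's background genes with an optimal summit within 500 bp of a start, for lists with at least 10 such genes, with exact 95% binomial intervals. The dashed line marks the 26.4% of all 7038 background genes, and the cytosolic ribosomal proteins stand at 66.3%.

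The DNA under the summits was rich in A and T. GC content within 100 bp of the summits averaged 35.5% (SD 7.68 across peaks), against 43.5% in flanks centred 500 bp away and 40.5% at the summits of the other candidates. The gap to the flanks was smaller in the strongest peaks labelled replicate 2 (38.7% against 42.8%) than in those labelled replicate 3 (34.5% against 43.8%). All of the 10 leading 6-mers were made of A and T alone. AAATAT was present within 100 bp of 55.8% of summits and in 27.7% of flanks (odds ratio 3.29, two-sided Fisher's exact adjusted p = 7.78e-142), with an odds ratio of 2.02 in the list labelled replicate 2 alone. It was followed by TTAAAA (49.3% against 24.1%), TAAATA (50.3% against 25.7%), ATATTA, AAAATA, ATTTTA, AATATA, AAATAA, ATTTAA and AATATT. In total 463 6-mers were higher at summits and present in at least 5% of them. With GC-matched candidate summits as the comparison, 38 were higher, and ACAGTG led (18.2% against 10.7%, odds ratio 1.86, Fisher's exact adjusted p = 4.46e-13). In that comparison the odds ratio of AAATAT was 1.29, and AAAATA, ATTTTA, AATATA and ATTTAA no longer passed (Fisher's exact adjusted p = 0.164, 0.155, 0.383 and 0.415).

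**Figure D4:**
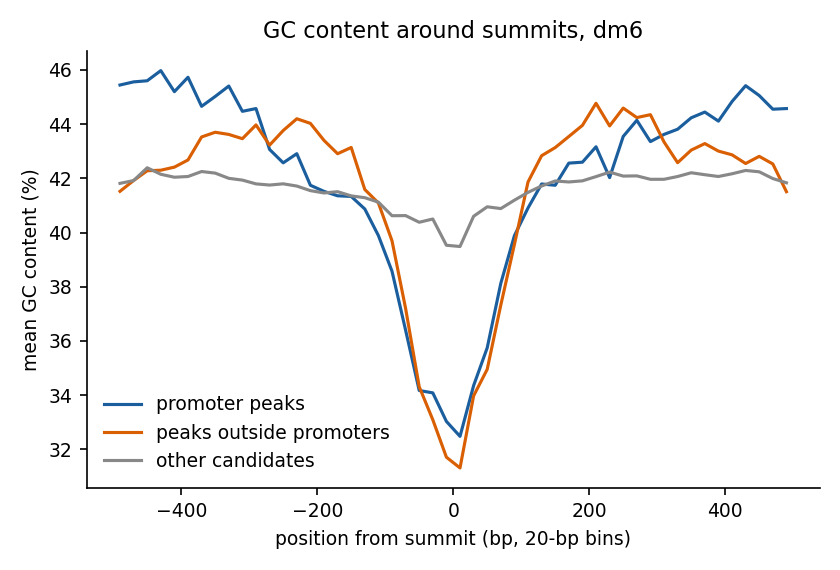
Mean GC content in percent, in 20-bp bins, by position in bp from the summit for promoter peaks, optimal peaks outside promoters and the other candidates. Over the central 41 bp it averages 32.7% in promoter peaks, 31.5% outside promoters and 39.5% in the other candidates.

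Of 30 known binding or core promoter consensus sequences, 12 were more frequent at summits than in the flanks and 8 less frequent. The DNA replication-related element TATCGATA, bound by Dref and BEAF-32, was present at 3.00% of summits against 0.371% of flanks (odds ratio 8.31, Fisher's exact adjusted p = 2.5e-23). Its odds ratio was 4.45 in the list labelled replicate 3 alone and 4.81 in the upper 50% of peaks. The Forkhead consensus (60.3% against 43.6%) and the Cad (33.8% against 24.0%) and Homeodomain (17.9% against 10.9%) consensus sequences were higher too, as was the ZIPIC consensus (1.52% against 0.253%). The GC-rich Mad/Med consensus (18.3% against 34.4%, odds ratio 0.427, Fisher's exact adjusted p = 4.44e-57, and odds ratio 0.653 in the list labelled replicate 2 alone) and the CA repeat (4.08% against 7.88%) were lower, the latter not in the list labelled replicate 2 alone (Fisher's exact adjusted p = 0.0914). With GC-matched candidates as the comparison, Ohler motif 7, Ohler motif 5, ZIPIC and Forkhead (odds ratio 1.22, from 1.97 against flanks) stayed higher, the GAGA element was higher, and none of the 30 was lower. The odds ratio of the DNA replication-related element was then 1.43 (Fisher's exact adjusted p = 0.119). That of the GAGA element was 1.94 in this comparison and 0.802 against flanks, where it was already on opposite sides in the 2 replicate lists, at 1.63 in the list labelled replicate 2 alone and 0.685 in that labelled replicate 3. Against flanks the GAGA element was lower still within 50 bp of the summit (odds ratio 0.408, Fisher's exact adjusted p = 2.52e-07). It was also lower outside promoters (0.524, Fisher's exact adjusted p = 2.33e-05). Outside promoters, the odds ratio of the DNA replication-related element was 0.666 against flanks, and that of ZIPIC was 2.34 (Fisher's exact adjusted p = 0.25), from 6.08 over all peaks. Ohler motif 7 was at 0.773 there and Ohler motif 5 at 0.833 (Fisher's exact adjusted p = 0.198 and 0.927), while Forkhead stayed higher at 1.84. The GC-matched candidates were not matched on location, so the larger promoter share of optimal summits was not held equal in that comparison.

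The CG6683 gene itself (FBgn0035902) lies on the minus strand at 3L 8513874 to 8514921, inside a gene on the other strand, CG6765. No optimal peak fell in it. Its own promoter had a candidate summit at 8514981, an offset of -60 bp, with a signal of 119 that ranked 5197 of 29984. Within 10000 bp of the gene lay 2 optimal peaks, at the CG43163 start (signal 412, rank 629 of 2964, 6557 bp from CG6683) and at the Pus7 start (signal 178, rank 2765, 3905 bp away). The same region held 14 pooled candidates, against 4.71 at the mean density of the arms. Those peaks cannot be assigned to the endogenous gene or the transgene copy by position alone.

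**Figure D5:**
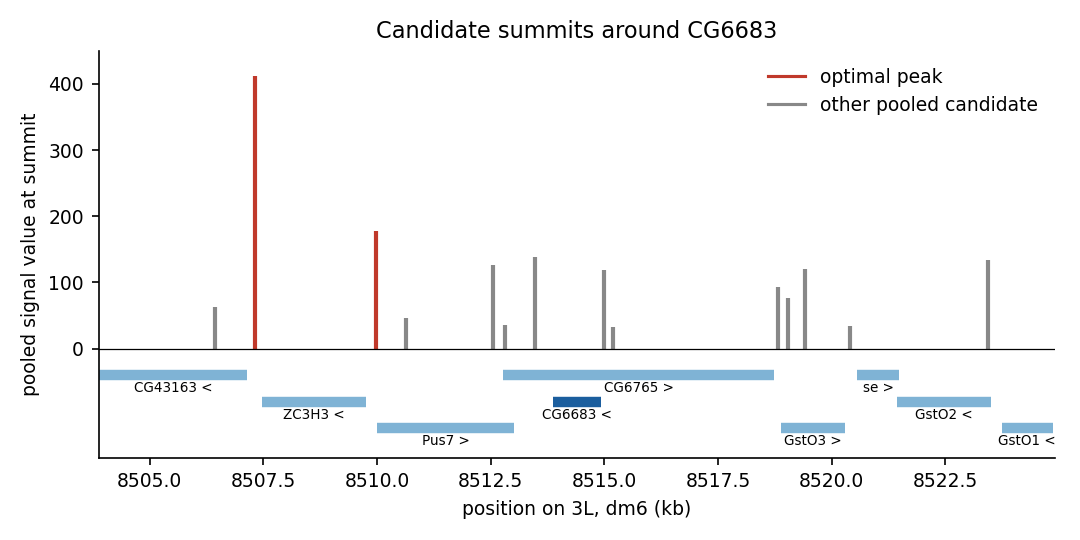
Pooled signal value, without units, at each candidate summit within 10000 bp of CG6683, by position on 3L in kb (dm6), with protein-coding genes drawn below to scale and their strand marked. The 2 optimal peaks (red) lie at the starts of CG43163 and Pus7, and the candidate at the CG6683 start has a signal of 119.

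The last comparison set the dm6 lists beside those on dm3. The dm3 optimal list held 3965 peaks, 2 of them mitochondrial. No coordinates were converted. On arm 2L, where most intervals carry the same coordinates in both builds, 383 of 555 dm6 optimal peaks (69.0%) were found with identical start, end and summit among the 726 dm3 optimal peaks on that arm, and their signal values had a Spearman rho of 1.00. The number was also 383 against all pooled dm3 candidates, while 91.5% of all pooled dm6 candidates had an identical one. Overlap was not compared, so peaks without an identical interval need not be absent from dm3.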

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

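Peaks on the mitochondrial genome drew attention because they lie outside the chromosome arms that the comparisons used. The optimal dm6 list held 16 of them, and they included the highest signal of the whole list, 7619, against 3257 for the highest peak on an arm. They came with the list labelled replicate 2 on dm6, which held 21 mitochondrial peaks reaching a signal of 7926, while the list labelled replicate 3 held 0. On dm3 the optimal list held 2, with a highest signal of 311. The dm3 list labelled replicate 3, which shares most intervals on 2L with the dm6 list labelled replicate 2, held 5 that reached 563. The mitochondrial peaks therefore differed between the builds as well as between the replicates.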

How the results depend on the processing

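All alternatives below were planned in advance. Replicate overlap, replicate signal correlation, promoter share, TSS offset, the number of annotation classes past the threshold and the peak count kept their direction and their side of the threshold, or stayed within 1.5 times, under every alternative run. Replicate overlap ranged from 53.2% to 70.2%, promoter share from 33.7% to 59.4%, the correlation from 0.577 to 0.702 and the median offset from -142 to -89 bp. Taking the upper part of the pooled list changed nothing, because it is the optimal list. The number of arms past the threshold was 2, and it was 1 against arm length, 3 on dm3, and ranged from 1 to 2 with a replicate left out. The higher signal at promoters ended with a 200 bp window (difference 7.84) and without replicate 3 (1.25, against 19.4 without replicate 2). The number of lists past the threshold went from 1 to 4 with all protein-coding genes as background, by construction, since genes without a candidate peak then count. Motifs higher at summits fell from 12 to 5 with GC-matched candidates and to 6 outside promoters. Motifs lower at summits went from 8 to 0 with GC-matched candidates, and ranged from 5 to 7 with a replicate left out. The 463 enriched 6-mers went to 38 with GC-matched candidates, of which 26 were among the 463. The cause was not tested in the other cases.

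Some single values turned round. Against arm length the X ratio was 1.02, because the X held more pooled candidates per Mb (254) than 2L, 2R, 3L and 3R (204 to 223). Intergenic summits were 16.9% with a 200 bp promoter window, and summits in non-coding genes were below the candidates among the upper 50% of peaks (1.55%) and without replicate 3 (1.45%, against 1.96% without replicate 2). With GC-matched candidates the odds ratio turned to 1.94 for the GAGA element, 0.816 for the TATA box, 0.839 for Su(Hw), 0.934 for Cad, 1.01 for Mad/Med and 1.18 for Ets. Outside promoters it turned to 0.666 for the DNA replication-related element, 0.800 for Ohler motif 1, 0.773 for Ohler motif 7 and 0.833 for Ohler motif 5. Among the upper 50% of peaks it was 0.952 for CTCF and 1.03 for Ets. For the GAGA element it was 1.63 without replicate 3 and 0.685 without replicate 2. Apart from the X ratio, the cause was not tested. Unknown read depth limits what the absence of a peak shows.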

Other observations

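Genes that start head to head with another gene more often had a CG6683-GFP peak within 500 bp, and intronic peaks lay more often in first introns. Both tests were set before their results were seen. Genes with an opposite-strand start within 500 bp upstream had a peak in 995 of 2963 cases (33.6%), against 860 of 4075 other background genes (21.1%), an odds ratio of 1.89 (95% interval 1.70 to 2.10, two-sided Fisher's exact p = 2.04e-31). Stratified by the number of candidate summits at the promoter it was 1.93 (95% interval 1.74 to 2.16). A peak within 500 bp of both starts counts for both genes, and the stratification does not remove this. The higher share therefore cannot show more peaks per promoter, and the p-value counts shared peaks more than once. Of the 1063 intronic summits, 768 (72.2%) lay in a first intron of a transcript, against 62.8% of the intronic candidates (odds ratio 1.54, 95% interval 1.34 to 1.77, Fisher's exact p = 5.02e-10).

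Core promoter elements within 100 bp of the start were compared between genes with and without a peak after the main results were seen, and 4 of 8 passed the adjusted threshold. An element or a peak at any start of a gene counted, so genes with more starts had more chances of both. No adjustment was made for this or for shared promoters. The GAGA element was present at 11.2% of the 1855 genes with a peak and 6.66% of the 5183 without (odds ratio 1.76, Fisher's exact adjusted p = 1.74e-08). Ohler motif 7 was present at 31.2% against 24.1% (odds ratio 1.43, Fisher's exact adjusted p = 1.74e-08). The DNA replication-related element was less frequent at genes with a peak (11.9% against 14.3%, Fisher's exact adjusted p = 0.0188), and Ohler motif 5 more frequent (6.90% against 5.13%, Fisher's exact adjusted p = 0.0149). Ohler motif 1, Ohler motif 6, the Initiator and the TATA box (6.09% against 6.44%) did not pass. Starts of long and other non-coding RNA genes lay within 500 bp of 4.86% of optimal summits against 3.05% of the other candidates (odds ratio 1.62, Fisher's exact adjusted p = 2.92e-06), while those of tRNA genes lay near 0.337% against 0.603% (adjusted Fisher's exact p = 0.145). Summits at protein-coding promoters were included in these counts. The non-coding gene class, which leaves such summits out, held 2.02% against 1.80% (Fisher's exact adjusted p = 0.384). Inside annotated transposable elements lay 4 optimal summits (0.135%) against 0.603% of the candidates (odds ratio 0.223, Fisher's exact adjusted p = 0.000908).

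For the ribosomal protein genes, the housekeeping test below was chosen after its values had been seen and the others before. If the peaks marked abundantly used housekeeping genes in general, the other housekeeping lists would share the excess, but together they had a peak at 59 of 232 genes (odds ratio 0.975, 95% interval 0.727 to 1.32), below the interval of the ribosomal protein list (3.50 to 8.84). The number of annotated starts and the GC content around them are also argued against as whole causes, since the stratified odds ratios were 5.50 (95% interval 3.43 to 8.84) and 5.55 (3.48 to 8.86). No biological explanation was tested, as the design has 1 group. An effect of very high transcription at these particular genes stays open.

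The low GC content at summits was weighed with tests chosen after it was seen. The composition of promoters is argued against as the cause, since outside promoters the central 41 bp were lower by a difference of -7.43 percentage points from the other candidates (95% interval -8.03 to -6.84). Bias of whole fragments towards low GC content was examined with candidates matched on GC within 100 bp of the summit. The difference at the centre was then -1.82 points (95% interval -2.42 to -1.21). The matched window contains the central 41 bp, so matching shrinks the difference there by construction. It is also at the short end of the stated fragments of 200 to 800 bp. Whether a fragment bias is the whole cause, or how much it contributes, therefore cannot be read from this test. In a wider window around the summit, GC content averaged 40.4% in optimal peaks and 41.3% in the other candidates. In flanks centred 500 bp away it was higher in optimal peaks, at 43.5% against 42.0%. A fragment bias as part or whole of the cause stays open. The depth of the dip also differed between the lists, with 35.9% GC over the central 41 bp in the strongest peaks labelled replicate 2 and 31.4% in those labelled replicate 3. No biological explanation was tested.

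ACAGTG led the 6-mers with GC-matched candidate summits as the comparison, and it was higher against flanks too (18.2% against 8.45%). A test set beforehand asked whether a word found on 1 chromosome held on others. The 8-mer with the lowest p on chromosome 2 was ACAGTGGG. On chromosomes 3 and X it was within 100 bp of 3.42% of 1841 summits against 1.41% of GC-matched candidates, an odds ratio of 2.47 (95% interval 1.55 to 3.87, two-sided Fisher's exact p = 9.08e-05). Of the 10 leading words from chromosome 2, 6 were higher there at an unadjusted Fisher's exact p under 0.05, while AAAAACAA (odds ratio 0.642) and GAAAAACA (0.626) were lower (Fisher's exact p = 0.000397 and 0.0159). The word was present at 104 of all 2964 peaks, at a median of 68 bp from the summit. The search ended 100 bp from the summit, so the word tended to lie nearer the edge of the window than its centre.

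The replicate numbers of the builds cross, as a test chosen after the fact describes. On arm 2L, 5023 of 5185 peaks (96.9%) of the dm6 list labelled replicate 2 had identical start, end and summit in the dm3 list labelled replicate 3, and 4791 of 5465 (87.7%) of the dm6 list labelled replicate 3 in the dm3 list labelled replicate 2. Lists of the same number shared 0. The widths of most peaks follow the same crossing, at 424 bp for dm6 replicate 2 and dm3 replicate 3, and at 450 bp for the other pair. An exchange of labels on one build is the likely source, and which build has the right number cannot be read from the lists. The candidates on chromosome 4 numbered 154 in the dm6 list labelled replicate 2 and 554 in that labelled replicate 3.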
